A study of Arabidopsis thaliana with 24 samples.

How the data were processed

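RNA abundance was measured in whole siliques with seeds at stages 3, 4 and 5 and in seeds without siliques at stages 6, 7, 8, 9 and 10 of Arabidopsis thaliana Col-0, with 3 arrays per group and 24 in all. Total RNA was labelled with biotin and hybridized to 1 Affymetrix ATH1 array per sample. The values deposited by the authors are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. Each array had been scaled by the authors: the mean of its signals between the 2nd and 98th percentiles lay between 100.008 and 100.01 on every array, next to a target of 100. This scaling makes each value relative to the rest of its array, so that a few very bright probe sets or a shift of most transcripts moves all others. The deposited data hold no detection calls, so low signals cannot be told from background by a call, and the number of arrays limits the precision. Growth conditions are labelled for stage 3 only.

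Samples were grouped by the tissue label, and replicates named by the letter in their titles (A, B, C in most groups, D, E, F in siliques stages 4 and 5, and A, B, D in seeds stage 10). Nothing in the labels pairs letters across groups, so the main model used none. There are 22810 probe sets. The 64 control probe sets were left out of the tests. A probe set was tested where its signal was above the 40th percentile of its array on at least 3 arrays, which left 16967. Signals were used as log2(signal + 6.97), the offset being the median over arrays of the 20th percentile, which shrinks the change of genes near the background.

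Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group and eBayes with a variance trend, 16 residual degrees of freedom), reading tables with data.table (version 1.17.8). Figures were drawn with matplotlib 3.10.9. A probe set was called where its Benjamini-Hochberg adjusted p was under 0.05 and its fitted change at least 2-fold. The 3 main comparisons were siliques stage 5 against 3, seeds stage 6 against siliques stage 5, and seeds stage 10 against 6, with 6 further steps between consecutive stages of the same material and a moderated F test over all groups. All alternatives, lists and rules described here were fixed before the data were examined, except where a choice is said to have been made later. "Rose" and "fell" are used only of called genes. Errors are SD of signals or SE of log2 changes.

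The annotation gives exactly 1 gene for 13513 probe sets, several for 503 and none for 8794, and 13436 of the 13513 matched a locus tag of the reference gene table. Tested probe sets with 1 gene numbered 9392 and covered 9311 genes, and 7575 tested probe sets had no gene or several and could not be named. Gene positions are not given in the sources used here. For each main comparison the genes named were the 8 highest and 8 lowest changes among called probe sets with 1 gene whose 3 arrays in 1 group lay all above or all below those in the other, and from each gene list 2 to 4 members by largest change, called ones before others. For each other step 2 highest and 2 lowest were named, and the 2 probe sets of smallest F test p. A gene without a symbol is named by its locus.

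The 20 gene lists hold 377 genes, of which 77 had a probe set of their own and 69 were tested, with the brightest probe set per gene. They cover seed storage proteins, oil body proteins, late embryogenesis abundant proteins and desiccation, seed maturation transcription factors, plastid fatty acid synthesis, photosynthesis, cell division, endosperm, seed coat flavonoids, seed coat mucilage, silique wall patterning, secondary cell wall, guard cells, pollen, sugar transport and reference genes. For 4 more lists, fatty acid modification and triacylglycerol assembly, abscisic acid, gibberellin, and embryo patterning, no gene could be tested, so they have no result. The reference genes were published as stable on arrays that included these samples, so their stability here is not independent evidence. The 11 lists with at least 3 tested genes were tested with camera (inter-gene correlation preset at 0.01, and again estimated) and fry, 33 tests in all, where the plan had counted 60. Of these 16 passed with the preset correlation, 12 with an estimated one and 29 by fry, which asks whether the genes of a list move on balance and does not compare them with other genes. The calls lost with an estimated correlation were those of pollen markers in both comparisons that use siliques stage 5, of oil body proteins in seeds stage 6 against siliques stage 5 and of storage proteins over the seed stages.

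The model was tested on simulated data with 100 changed probe sets at 4-fold and at 1.5-fold. At 4-fold 100% were called in each of the 3 main comparisons. At 1.5-fold 63%, 59% and 56% passed the adjusted p in siliques stage 5 against 3, seeds stage 6 against siliques stage 5 and seeds stage 10 against 6, and 0%, 2% and 1% were called, as the minimum fold demands. Of the unchanged probe sets 2, 0 and 1 were called. The simulated changes were added after the offset, so its shrinkage of low signals was not simulated. Far fewer probe sets changed than were called in the real comparisons. The shares called are therefore not the sensitivity for genes near the background. Of 200 simulated lists of 5 unchanged genes, 3, 5 and 3 had a camera p under 0.05. The simulated genes were drawn independently of each other, whereas the estimated correlation in the real lists reached 0.38. These counts therefore do not test the preset correlation.

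Alternatives were tried for the scaling between arrays (quantile normalization, centring on the reference genes, centring on the 75th percentile), the offset (none, and 4 times larger), the filter (none, and the 60th percentile), the variance model (no trend, robust), the arrays in the fit (only the 2 groups compared, each array left out in turn), the title letters as a block, the threshold (adjusted p under 0.01, no minimum fold), and for lists the correlation, the mean over a gene's probe sets and fry. Fits without the 6 arrays of 25S ribosomal RNA signal over 1000, and with that signal as a covariate, were added after seeing the control probe sets. The fit without these arrays leaves array B alone at seeds stages 8 and 10, so no result there rests on it.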

Results

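The series followed siliques and seeds of Arabidopsis thaliana, accession Col-0, on Affymetrix ATH1 arrays, which read transcripts with short probes grouped into probe sets. The 24 arrays fell into 8 groups of 3. Whole siliques with the seeds inside were taken at stages 3, 4 and 5, and seeds without siliques at stages 6, 7, 8, 9 and 10. The labels number the stages without days, and nothing in them says that the 3 arrays of a group came from separate plants, so the p-values measure the spread between these samples, which may be technical. Within a group the log2 values of 2 arrays correlated at 0.971 to 0.993 across probe sets, which are not independent replicates.

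Nearly every tested probe set moved over the series. The moderated F test over the 8 groups passed for 16103 of 16967 probe sets (94.9%). M10, a late embryogenesis gene, had the smallest p, with signals of 0.514 ± 0.263 (SD, n = 3) in siliques stage 4, 75.4 ± 7.91 in seeds stage 7 and 5800 ± 214 in seeds stage 10. It was followed by AT3G17520, another late embryogenesis gene, which stood at 0.615 ± 0.305 in siliques stage 3 and 8060 ± 844 in seeds stage 10. Of the 16967 probe sets, 4411 (26%) had their highest group mean in siliques stage 3 and 3553 (20.9%) in seeds stage 10.

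The arrays also differed in other ways, some of which follow the stage. The 10 brightest probe sets held 1.32% ± 0.0331 of the summed signal in siliques stage 3 and 3.53% ± 0.436 in seeds stage 9, while the median signal ranged from 42.6 down to 32.8. The control probe sets for GAPDH, a glycolytic enzyme, read 2592 ± 74.7 at the 3' end in seeds stage 6, 406 ± 36.6 in stage 8 and 155 ± 10.7 in stage 10. The 25S ribosomal RNA control was at most 127 in the siliques, but over 1000 on 6 seed arrays, namely stage 6 A, stage 7 C, stage 8 A and C, and stage 10 A and D.

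The comparison of siliques stage 5 with stage 3 followed whole siliques, the wall and the seeds together. The share of each in the RNA was not measured. A change in that share therefore cannot be separated from a change of expression within the seeds or the wall. The title letters differ between these groups (D, E, F at stage 5 and A, B, C at stage 3), so a batch tied to them, if there was one, cannot be separated from the stage. Genes for seed reserves were among the steepest increases, with 3 of the 8 highest changes. The storage protein genes AT4G36700 and AT2G28490, both cupins, rose from signals of 0.863 ± 0.418 and 4.92 ± 2.35 (SD, n = 3) to 2270 ± 156 and 1970 ± 177. The oleosin genes AT3G01570 and OLEO3, for coat proteins of oil bodies, rose from 10.8 ± 7.42 and 20.5 ± 2.81 to 3270 ± 105 and 3280 ± 77.5. Among the genes that fell were the subtilase gene AT4G21630, from 931 ± 45.5 to 4.38 ± 1.54, and the endosperm marker MPC, from 85.1 ± 12.7 to 9.8 ± 2.46.

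Of 5 tested storage protein genes 4 rose and 1 was not called. PAP85, a vicilin-like gene, rose by 6.61 ± 0.10 (SE) on the log2 scale and the cruciferin gene AT1G03890 by 6.29 ± 0.11, whereas AT2G18540 had a log2 difference of 0.98. All 3 oil body genes rose, AT2G25890 by 2.57 ± 0.13. Of 14 late embryogenesis abundant genes, whose proteins protect drying seeds, 9 rose and 5 were not called. AT3G17520 rose by 3.83, AT4G21020 by 3.40, AT5G44310 by 2.98 and AT3G15670 by 2.16 (0.99 and not called with an offset 4 times larger), while M10 read 0.53 ± 0.347 at stage 3 and 0.521 ± 0.112 at stage 5. Of 7 genes of plastid fatty acid synthesis 6 rose, among them the thioesterase gene FaTA by 2.56, AT4G13050 by 1.53, AT5G10160 by 1.49 and the ketoacyl reductase gene AT1G24360 by 1.19, and FATB, at 0.23, was not called. These 4 lists passed camera with adjusted p = 1.5e-07 (storage), 2.9e-05 (oil bodies), 1.9e-06 (late embryogenesis) and 7.9e-05 (fatty acids), and also with an estimated correlation, at adjusted p = 0.012, 0.016, 0.016 and 0.029.

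Both tested sugar transporters rose, SAG29 (also SWEET15) from 42.2 ± 11.6 to 963 ± 48.6 and SWEET11 from 153 ± 7.52 to 1580 ± 19.9. Of 2 maturation transcription factors EEL rose by 4.02, and BZIP53 had a log2 difference of 0.27. Of 4 seed coat mucilage genes 2 rose, the peroxidase gene AT3G50990 (PRX36) by 4.03 and the subtilase gene ARA12 (SBT1.7) by 1.24; AT3G10320 and AT2G22900 had differences of 0.84 and 0.40, the former reaching 1.02 and a call with no offset. The mucilage list passed camera with adjusted p = 0.007, and 0.026 with an estimated correlation. Of 4 silique wall genes the polygalacturonase gene ADPG1 rose by 2.25 and SPT by 1.61. ALC, at -0.97, and YAB3, at 0.86, were not called, and ALC reached -1.03 and a call without stage 3 replicate B or with quantile normalization. With no offset both were called. GUT2 (IRX10), a xylan synthesis gene and the only tested gene of the secondary cell wall list, rose by 1.42.

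Lower at stage 5 were both endosperm markers, MPC at -2.46 and AT4G36590 at -1.42 (-0.72 and not called with an offset 4 times larger). Of 3 pollen markers 2 fell, AT5G45880 from 1570 ± 16.6 to 232 ± 5.94 and the receptor kinase gene ANX2 from 87.8 ± 4.99 to 10.5 ± 3.21, and MGH3, a histone gene of sperm cells, had a difference of -0.77. The pollen list passed camera with adjusted p = 0.029, a call lost at adjusted p = 0.13 with an estimated correlation, the highest of its alternatives, which began at 0.005. Of 2 guard cell markers AT1G22690 (GC1) fell by 1.45, but was not called at -0.89 with an offset 4 times larger, and FMA (FAMA) was not called, at -0.53. No gene was called among 7 for photosynthesis (median -0.29, LHCB4.2 at -0.90, or -1.23 and called with quantile normalization, PSAN at -0.63), 4 for cell division (AUR2 at -0.40, PRL at 0.13), 3 for seed coat flavonoids (DFR at -0.77, BAN at -0.70) or 6 reference genes (median 0.03, and -0.02 with quantile normalization). The reference genes were published as stable over arrays of the same collection, so their count is not independent of these samples. In the same arrays the actin 3'/5' signal ratio, a sign of RNA quality, was 4.09 ± 0.288 at stage 3 and 2.67 ± 0.200 at stage 5, and that of ubiquitin 1.86 ± 0.108 and 1.52 ± 0.0629.

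Outside the lists, the highest changes from siliques stage 3 to 5 were those of AT1G62070, from 0.509 ± 0.235 to 3180 ± 120, of AT5G38170 and AT5G38160, members of the lipid transfer protein superfamily, at 7.68 and 7.64, of AT3G63040 at 7.61 and of AT1G47540 at 7.09. Besides AT4G21630, named above, the lowest were those of AT3G24510, which fell by 6.61, AT2G30810, by 5.81, and AT3G49270, by 5.66. AT5G47350 fell by 5.52, and the lipase genes AT4G28780 and AT1G54020, at -5.43 and -5.25, and LCR24, for a small cysteine-rich protein, at -5.03, were lower as well. In all 1770 probe sets rose and 1844 fell, 136 of the former and 52 of the latter by over 16-fold. The 3 arrays of 1 group lay all above or all below those of the other for 71.1% of tested probe sets, where 10% would do so by chance. Every list gave the same counts adjusted over the list alone. Many of these genes sat among the low signals of the array in 1 of the groups, so that their fold depends on the offset added before the logarithm.

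**Figure D1:**
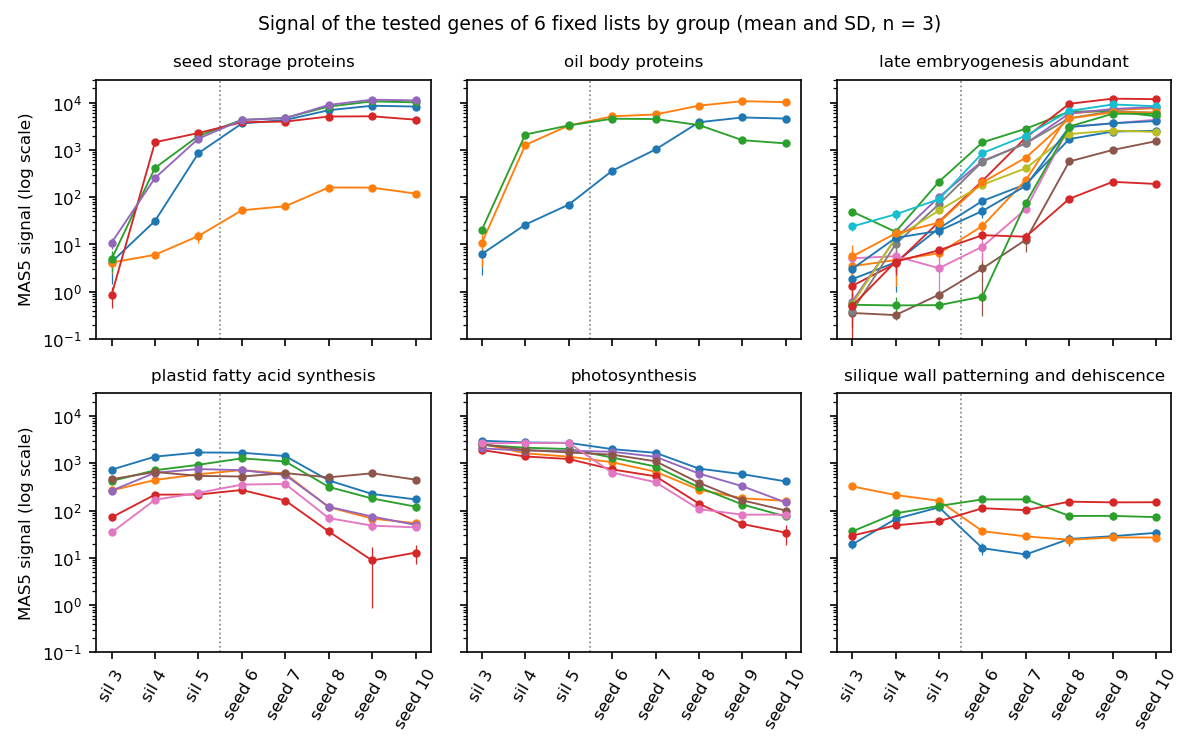
Mean MAS5 signal (vertical log axis, arbitrary units) of the tested genes of 6 lists in the 8 groups, siliques (sil) left and seeds right of the dotted line; each line is 1 gene, bars are the SD of 3 arrays, shortened below where the SD exceeds the mean. PAP85 in the storage panel read 4270 by seeds stage 6, while M10 in the late embryogenesis panel rose from 0.791 in stage 6 to 5800 in stage 10 and all 7 photosynthesis genes fell from stage 6 to stage 10.

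Seeds stage 6 were compared with siliques stage 5, the neighbouring stages across the change of material, so that the removal of the silique wall and the later stage cannot be separated. The title letters change too, from D, E, F to A, B, C, so a batch tied to them, if there was one, cannot be separated either. Some genes read strongly in whole siliques were close to absent from seeds. ECS1 fell from 1560 ± 89.4 to 10.5 ± 5.54 (SD, n = 3), the lipid transfer protein gene AT2G45180 from 865 ± 88.1 to 11.7 ± 5.17 and PIFI, for a chloroplast protein, from 918 ± 18.1 to 15.3 ± 2.07. RCA, which activates Rubisco, fell from 2690 ± 185 to 634 ± 43.4. Of the late embryogenesis genes, AtLEA4-1 was higher in the seeds, at 855 ± 52.6 against 90.7 ± 5.66.

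Of 14 late embryogenesis abundant genes 10 were higher in seeds stage 6 and 4 were not called. AtLEA4-1 rose by 3.14 ± 0.12 (SE), AT4G21020 by 2.87, AT3G02480 by 2.72 and AT3G15670 by 2.63. Storage protein genes were higher for 4 of 5, AT1G03890 by 2.07, AT2G18540 by 1.45, PAP85 by 1.30 and AT2G28490 by 1.13. For AT2G28490 the difference was 0.95 and no longer called with the arrays centred on the reference genes, and for AT2G18540 0.91 and not called with an offset 4 times larger. Both lists passed camera, the late embryogenesis list with adjusted p = 7.1e-10 and the storage list with 4.4e-05, and with an estimated correlation at 0.0047 and 0.029. Of 3 oil body genes AT2G25890 rose by 2.26, while AT3G01570 and OLEO3 had differences of 0.64 and 0.47. The oil body list passed with adjusted p = 0.017, a call lost at adjusted p = 0.12 with an estimated correlation, in a range from 0.004. EEL rose from 259 ± 8.04 to 700 ± 18.5, and BZIP53 had a difference of 0.23.

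Of 7 photosynthesis genes RCA fell by 2.07 and 6 were not called, with PSAN at -0.72, PSAE-1 at -0.60 and LHCB4.1 at -0.45. The list was lower with adjusted p = 0.00078 by camera and 0.015 with an estimated correlation. Of 4 silique wall genes ADPG1 fell from 117 ± 9.84 to 16 ± 4.35 and ALC, a transcription factor of the valve margin, from 161 ± 4.28 to 36.6 ± 4.86, while YAB3 and SPT had differences of 0.85 and 0.44. GUT2 fell by 1.30. Of the pollen markers AT5G45880 fell from 232 ± 5.94 to 55.7 ± 8.37, and ANX2, at -0.91, and MGH3, at -0.01, were not called, although ANX2 was called at -2.47 with no offset, -1.09 with the arrays centred on the reference genes, -1.06 without siliques stage 5 replicate E and -1.08 without seeds stage 6 replicate C. The pollen list had adjusted p = 0.046, which became 0.061 without seeds stage 6 replicate A and 0.058 without siliques stage 5 replicate F, and adjusted p = 0.16 with an estimated correlation; over its 16 alternatives it ranged from 0.027 to 0.16. No member was called of the lists for fatty acid synthesis (FaTA at 0.57, AT2G34590 at 0.45), cell division (AUR1 at -0.36, PRL at -0.10), endosperm (MPC and AT4G36590, each at 0.23), seed coat flavonoids (UGT80B1 at -0.52, BAN at -0.48), mucilage (AT3G50990 at -0.77, ARA12 at -0.52), guard cells (AT1G22690 at -0.26, FMA at -0.20), sugar transport (SAG29 at 0.56, SWEET11 at 0.07) and reference genes, a list not independent of these samples (AT2G28390 at 0.39, AT4G26410 at -0.11).

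Beyond the lists, the steepest rises in seeds stage 6 were those of AT2G22510 at 4.05, the peroxidase gene AT1G68850 at 4.00, AT5G45690 at 3.92 and AT1G27461 at 3.88. They were followed by AT5G07330 at 3.61, the methionine sulfoxide reductase gene MSRB6 at 3.59, AT5G20860, for a pectin methylesterase, at 3.58, and AT4G38080 at 3.48. Of the steepest falls all but the last ended among the low signals of the seed arrays, so that their size and order depend on the offset: ECS1 at -6.54, AT1G22480 at -6.30, AT2G45180 at -5.58, AT3G28270 at -5.47, PIFI at -5.38, AT1G23130 at -5.24, AT3G62550 at -5.19 and AT2G25510 at -5.10. The ubiquitin 3'/5' ratio was 1.47 to 1.59 in siliques stage 5 and 1.60 to 2.03 in seeds stage 6, that of actin 2.67 ± 0.200 and 3.01 ± 0.186, and the 25S control at most 31.3 and 68.8 to 2074, and the differences given here were not separated from these. In this comparison 690 probe sets were higher in seeds and 1282 lower, and of the changes over 16-fold 3 were higher and 38 lower. Adjusted over the list alone each list gave the same counts. Centring on the reference genes moved the median of all probe sets from 0.06 to -0.12 and gave 499 higher and 1635 lower, so that higher calls made up 23.4% instead of 35%.

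Over the isolated seeds, stage 10 was compared with stage 6, the last and the first of the seed stages sampled. Some late embryogenesis genes came up from low signals, M10 from 0.791 ± 0.138 to 5800 ± 214 (SD, n = 3) and AT3G53040 from 8.99 ± 4.58 to 4350 ± 300. BGLU19, a beta-glucosidase gene, rose from 2.29 ± 0.731 to 6120 ± 777, and LCR67, for a small cysteine-rich protein, from 1.09 ± 1.07 to 4160 ± 162. The photosystem gene PSAN fell from 740 ± 14.2 to 34 ± 15, the fatty acid synthesis gene AT5G10160 from 714 ± 30 to 49.7 ± 7.41, and BAN, for anthocyanidin reductase of the seed coat, from 784 ± 6.21 to 29.2 ± 14.6.

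All 14 late embryogenesis abundant genes rose, by a median of 4.84 and by 1.83 to 9.55 on the log2 scale. After M10 came AT3G53040 at 8.13 ± 0.18 (SE), AT2G42560 at 7.93 and AT3G22490 at 7.31. The list passed camera with adjusted p = 4.5e-12, and 0.0023 with an estimated correlation. Of the 5 storage protein genes 4 rose, PAP85 by 1.37, AT2G28490 by 1.22, AT1G03890 by 1.19 and AT2G18540 by 1.09, and AT2G18540 fell short of a call at 0.95 without seeds stage 6 replicate C and at 0.87 with an offset 4 times larger. The storage list passed with adjusted p = 0.027, a call lost at adjusted p = 0.17 with an estimated correlation. With quantile normalization PAP85, AT1G03890 and AT2G28490 stood at 0.15, 0.15 and 0.03 and the list had adjusted p = 0.9, the highest of a range from 0.013. The 3 oil body genes parted: AT2G25890 rose by 3.65, OLEO3 fell from 4550 ± 178 to 1370 ± 80.8, and AT3G01570, at 0.99, was not called, though it reached 1.01 without seeds stage 6 replicate A, 1 without replicate C and 1.08 without seeds stage 10 replicate A. Their median of 0.99 became -0.21 with quantile normalization, and the list was not called (adjusted p = 0.64). BZIP53 rose by 1.17, and EEL, at 0.78, was not called. With the arrays centred on the reference genes EEL was called at 1.21 and AT3G01570 at 1.42, and the latter at 1.10 with centring on the 75th percentile.

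All 7 photosynthesis genes fell, PSAN by 4.25, PSAE-1 by 4.02, PSBY by 3.83 and PSBW with a change of -3.51, and the list passed with adjusted p = 1.1e-06, and 0.0023 with an estimated correlation. Of 7 fatty acid synthesis genes 6 fell, AT4G13050 with a change of -3.86, AT5G10160 with -3.68, AT2G22230 with -3.58 and AT2G34590 with -3.33, and FATB was not called at -0.22; the list had adjusted p = 2.9e-05, and 0.026 with an estimated correlation. Of 4 mucilage genes AT3G50990 fell by 3.16, the galactosyltransferase gene AT2G22900 (MUCI10) by 2.42 and ARA12 by 2.04, with adjusted p = 0.023 for the list and 0.048 with an estimated correlation. Of 3 flavonoid genes BAN fell by 4.52 and DFR, for dihydroflavonol reductase, by 2.27, while UGT80B1 had a difference of 0.39. The flavonoid list was not called, with adjusted p = 0.11 and a range of 0.049 to 0.18 over its alternatives. Among cell division genes the kinase gene AUR1 fell by 1.95, PRL (MCM7) from 106 ± 10.9 to 27.9 ± 3.96 and the polymerase gene ICU2 by 1.24, and AUR2 was not called at -0.40. ICU2 lost its call with the arrays centred on the reference genes (-0.81) and with an offset 4 times larger (-0.54). Their list had adjusted p = 0.056, and 0.045 without seeds stage 10 replicate D, within a range of 0.017 to 0.15.

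Of the silique wall genes SPT fell by 1.18, and ADPG1 at 0.84, YAB3 at 0.40 and ALC at -0.36 were not called. With the arrays centred on the reference genes SPT stood at -0.74 and lost its call, as it also did with an offset 4 times larger, and ADPG1 gained a call at 1.27, and at 1.11 with no offset. GUT2 at -0.37, the guard cell markers FMA and AT1G22690 at 0.71 and 0.36, and the transporters SWEET11 and SAG29 at -0.57 and 0.21 were not called either, but FMA was, at 1.14, with the arrays centred on the reference genes. The endosperm marker AT4G36590 rose by 1.01, but stood at 0.95 without seeds stage 6 replicate A, 0.97 without replicate C 0.87 without seeds stage 10 replicate D, 0.97 with quantile normalization and 0.52 with an offset 4 times larger, below a call each time, and MPC was at 0.29. The pollen marker AT5G45880 rose from 55.7 ± 8.37 to 195 ± 25.4, while MGH3 and ANX2 had differences of -0.15 and 0.06. None of the 6 reference genes, a list not independent of these samples, was called, with AT5G46630 at -0.58, AT4G34270 at -0.53 and a median of -0.19, which became 0.24 with the arrays centred on these genes.

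Further genes at the extremes of the seed comparison were AT1G14940 at 8.73 and AT1G14930 at 8.55, relatives of major latex proteins, and the lectin gene AT3G21380 at 8.23, all from low signals in stage 6, so that the fold depends on the offset, as it does for several of the falls. The pectin methylesterase gene ATPMEPCRD fell by 6.06, the protease gene AT1G09750 by 5.80, GILT, for a thiol reductase, by 5.70 and CHIL, a relative of chalcone isomerase, by 5.64. The glutathione transferase gene GSTU20 fell by 5.50, AT5G38180 by 5.38, the protease gene AT3G54400 by 5.31 and the germin-like gene AT5G39130 by 5.26. In total 2389 probe sets rose and 3346 fell. The ubiquitin 3'/5' ratio was 1.60 to 2.03 in stage 6 and 2.06 to 2.28 in stage 10, and that of actin 3.01 ± 0.186 and 2.17 ± 0.140. Counts adjusted over the list alone did not differ from those over all probe sets for any list. The balance of directions depended on the scaling. Centring on the reference genes moved the median of all probe sets from 0.02 to 0.45 and gave 4568 higher and 2173 lower (67.8% higher instead of 41.7%), and centring on the 75th percentile moved it to 0.13 with 2797 higher and 3005 lower.

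Probe sets called over the siliques (stage 5 against 3) and over the seeds (stage 10 against 6) overlapped in part. The former comparison read whole siliques and the latter seeds alone, so the material differs between them. Of the 1770 that rose in siliques, 652 (36.8%) fell in seeds, against 349.1 if the calls were independent (odds ratio 2.71, adjusted p = 1.8e-70, Fisher's exact test, two-sided, 4 tests). AT4G13050, AT5G10160, FaTA and AT1G24360 of fatty acid synthesis, ARA12 and AT3G50990 of mucilage, and SPT were among them. Rises in both numbered 305, against 249.2 (odds ratio 1.31, adjusted p = 0.00016), and included storage and late embryogenesis genes such as PAP85 and AT3G17520. Falls in both numbered 371, against 363.6 (adjusted p = 0.64), and 208 that fell in siliques rose in seeds, against 259.6 (odds ratio 0.754, adjusted p = 0.00025). Probe sets are not independent of each other, and both comparisons share the variance estimate.

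Between consecutive stages the changes came in large and small steps. The labels give no days, so the steps may span unequal times and their sizes are not rates. From siliques stage 3 to 4 the storage gene AT4G36700 rose by 7.53 and the oleosin genes OLEO3 and AT3G01570 by 6.27 and 6.26. Storage genes rose for 4 of 5, oil body genes for 3 of 3, both sugar transporters rose, and all 3 pollen markers fell, AT5G45880 from 1570 ± 16.6 to 225 ± 7.08 (SD, n = 3). The actin 3'/5' ratio was 4.09 ± 0.288 in stage 3 and 2.67 ± 0.228 in stage 4. AT1G62070 and AT5G38170 led the rises, at 8.25 and 7.54, and the lipase gene AT5G33370 fell from 1620 ± 0.499 to 13.9 ± 7.88 and AT4G21630 by 6.12. In all 1595 probe sets rose and 1605 fell. From stage 4 to 5 the number was 320 and 244, led by AT1G62210 at 4.74 and AT5G09480 at 4.53, with AT5G47350 at -3.56 and AT3G49270 at -3.21. At these and the later steps too, the fold of genes with a low signal at 1 of the stages depends on the offset.

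**Figure D2:**
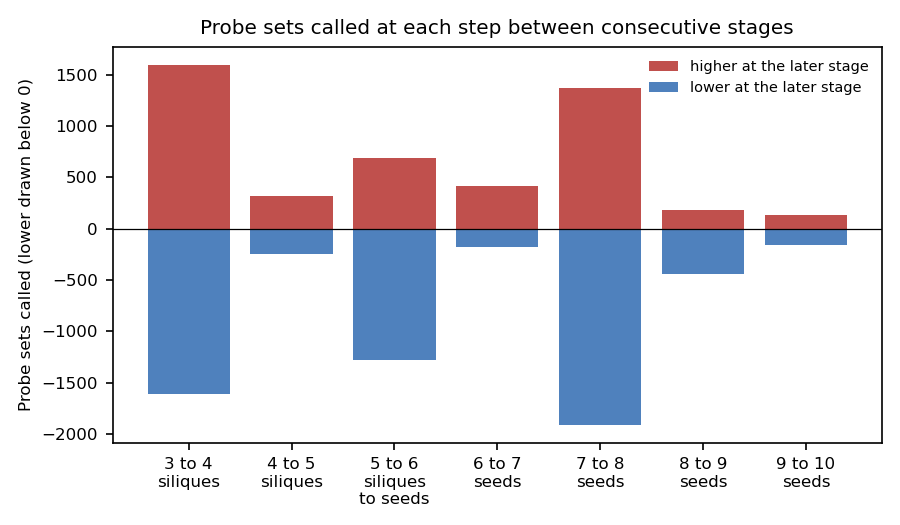
Number of probe sets called higher (above 0) and lower (drawn below 0) at each of the steps between consecutive stages; the step from stage 5 to 6 also changes the material from siliques to seeds. The steps from stage 3 to 4 (3200 calls) and from 7 to 8 (3275 calls) exceeded the other steps within siliques or within seeds, which gave 291 to 623.

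Within seeds the step from stage 7 to 8 stood out. All 14 late embryogenesis genes rose, AT3G53040 from 56.3 ± 9.22 to 3080 ± 129 (SD, n = 3), M10 by 5.24 and AT3G22490 by 4.92, and all 7 photosynthesis genes fell, PSAN by 1.88 and RCA by 1.83. Of 7 fatty acid synthesis genes 6 fell, FaTA from 365 ± 36.4 to 69.2 ± 14.8. The dioxygenase gene AT5G54000 rose by 6.25, and ATPMEPCRD and AT4G30650 fell by 4.70 and 3.88. This step gave 1367 higher and 1908 lower, 5.51 times the calls of the step before and 5.26 times those of the step after. Centring on the reference genes turned the balance to 3224 higher and 830 lower (79.5% higher instead of 41.7%), with a median of all probe sets of 0.45.

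The other seed steps were smaller. From stage 6 to 7, 412 probe sets rose and 182 fell, 11 of 14 late embryogenesis genes rose, and AT2G18370, for a lipid transfer protein, and AT1G54870 rose by 4.90 and 4.54, while AT3G10040 and AT4G15750 fell by 2.93 and 2.72. Centring on the reference genes gave 336 and 296 with a median of -0.16, or 53.2% higher instead of 69.4%. From stage 8 to 9, 180 rose and 443 fell, led by AT5G15950, an S-adenosylmethionine decarboxylase gene, at 2.50, AT1G55450 at 2.49, GILT at -5.64 and AT1G56100 at -4.99. From stage 9 to 10, 132 rose and 159 fell. AT4G10270 and AT1G19210 rose by 2.64 and 2.19, and AT5G15950 and AT4G30650 fell by 2.68 and 2.22. For this last step centring on the reference genes gave 182 higher and 122 lower (59.9% higher instead of 45.4%).

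Several of the genes named for these steps turned direction at seeds stage 8. GILT went from 706 ± 46.6 in stage 7 to 1840 ± 130 in stage 8 and 30 ± 1.73 in stage 9 (SD, n = 3). AT4G15750, of the pectin methylesterase inhibitor superfamily, went from 88.3 ± 3.68 to 1150 ± 224 and 47 ± 5.22, and AT1G56100, of the same superfamily, from 67.5 ± 3.79 to 710 ± 159 and 15.3 ± 2.22. AT5G47350, at 2020 ± 128 in siliques stage 3, went from 10.7 ± 3.49 to 298 ± 33.7 and 18 ± 2.52. AT4G10270 read 212 ± 11, 1610 ± 110, 124 ± 10.1 and 815 ± 100 in stages 7, 8, 9 and 10, and AT5G15950 took the opposite course with 906 ± 91.1, 203 ± 28.8, 1170 ± 34.2 and 178 ± 12.9. In all 91 probe sets rose from stage 7 to 8 and fell from 8 to 9, and 30 did the reverse, a pattern sought after these values were seen. Both steps use the same 3 arrays of stage 8. An error or technical shift in those arrays would by itself give calls in opposite directions, so the counts alone do not show a turn in the seeds.

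**Figure D3:**
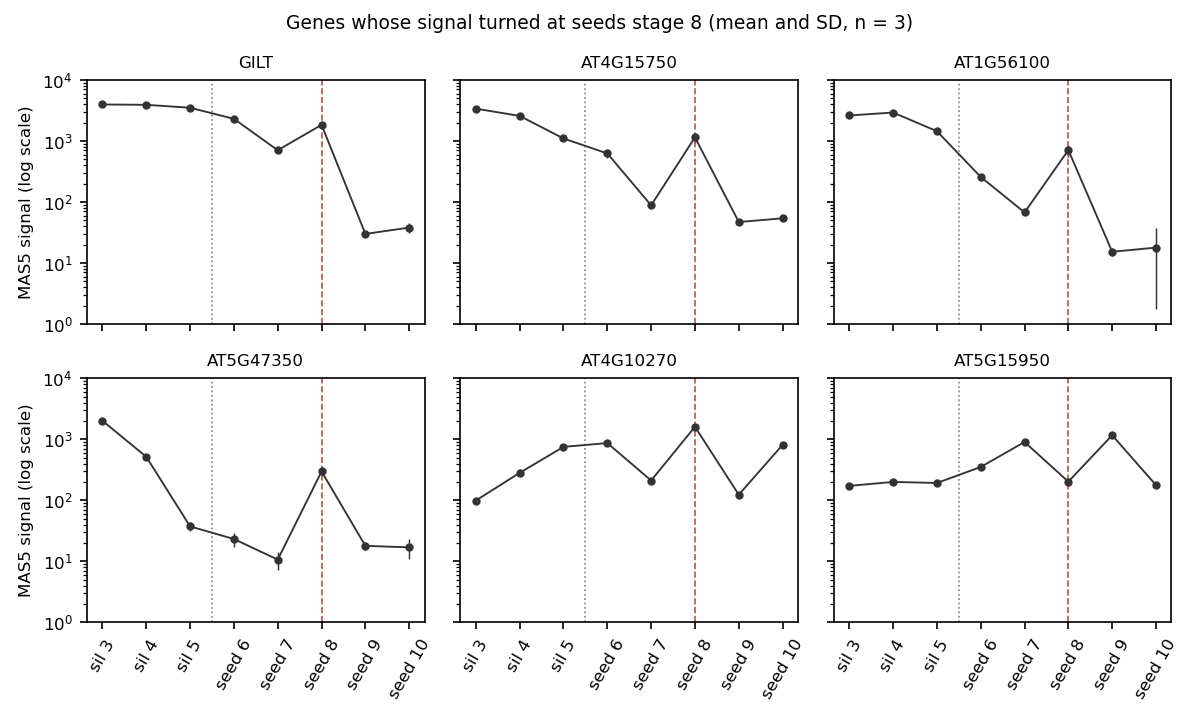
Mean MAS5 signal (vertical log axis, arbitrary units) of 6 genes in the 8 groups, siliques (sil) left and seeds right of the dotted line; bars are the SD of 3 arrays, shortened below where the SD exceeds the mean, and the dashed line marks seeds stage 8. GILT, AT4G15750, AT1G56100, AT5G47350 and AT4G10270 peaked at stage 8 among the neighbouring stages, while AT5G15950 dipped to 203 there.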

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

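The tests of the title letters, 5' ends, pollen and mixed tissue, and the scaling test of the step from stage 3 to 4, were chosen after the result was seen, as was the count with the 25S covariate for the step from stage 7 to 8, and both fits that involve the 25S signal after the control probe sets were seen. The 25S ribosomal RNA control, a probe set outside the comparisons, read 4717 on seeds stage 8 A and 4242 on stage 8 C against 119 on stage 8 B, and 3702, 933 and 2887 on seeds stage 10 A, B and D. With that signal as a covariate limma found 0 of 16967 probe sets (0%) that followed it at an adjusted p under 0.05 and 1061 at an unadjusted p under 0.05, where 848.4 would do so by chance. The authors' scaling removes a displacement shared by all signals, which this test was therefore unable to see, so displacement of other signals by ribosomal RNA stays open.

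From siliques stage 3 to 4 the calls numbered 3200, and from stage 4 to 5, 564. Quantile normalization gave 3256 calls for the step from stage 3 to 4, and centring on the reference genes 1496 higher and 1719 lower. The number of calls thus did not hang on these scalings. A shift of most transcripts stays open, since quantile normalization also takes the arrays to have like distributions. Pollen carried on the stage 3 siliques may account for part of the lower calls: its 3 tested markers fell by a median of -2.37, lower than all but 0.42% of 10000 random lists of matched signal, the most abundant being AT5G45880 (1570 ± 16.6 to 225 ± 7.08), which also read 195 ± 25.4 in seeds stage 10. Loss of 5' ends at stage 3 cannot be told apart from the stage, since the 3'/5' log2 ratio was higher at stage 3 by a median of 0.55 (actin 0.62 ± 0.09 SE, ubiquitin 0.55 ± 0.05, GAPDH -0.07 ± 0.03), between the bounds set for and against it. A batch tied to letters D to F cannot be told apart either, as only 1 seed array carries the letter D (slope of its deviation on the step, -0.01), and a developmental change, untested, stays open along with loss of pollen RNA as a source of the higher calls, on which the median change of all probe sets (-0.02) decides nothing, being held near 0 by the authors' scaling.

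From seeds stage 7 to 8, 3275 probe sets were called, with M10 and AT3G53040 among the rises. Quantile normalization gave 3144 calls and centring on the reference genes 3224 higher and 830 lower. The large number of calls thus did not hang on these scalings, but the balance of directions did. A shift of most transcripts stays open, since quantile normalization also takes the arrays to have like distributions. The fit with the 25S signal as a covariate gave 3270 calls, but 0 probe sets followed that signal, so the count could hardly move. It decides nothing on a displacement shared by all signals, which stays open. The fit without the 6 arrays of high 25S signal, which leaves 1 array at stage 8, was not used here. Loss of 5' ends as the whole cause is argued against by the 3'/5' log2 ratios, which differed between stages 8 and 7 by a median of 0.14 (actin 0.09 ± 0.12 SE, ubiquitin 0.44 ± 0.13, GAPDH 0.14 ± 0.13). A change in the seeds themselves between these stages is a candidate explanation that no test here isolates, and other differences in handling stay open.

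Signals that returned at seeds stage 8 include GILT, AT4G15750 and THI2.1, a thionin gene singled out after its values were seen (2980 ± 177 in siliques stage 3, then 23.4 ± 4.54, 269 ± 21.5 and 29.3 ± 7.07 in seeds stages 7, 8 and 9). Of the 91 probe sets that rose from stage 7 to 8 and fell from 8 to 9, 46 were highest in siliques, 27 of them at stage 3. Another 39 were highest in seeds stage 8 and 6 in seeds stage 10, so not all of the 91 returned to an earlier level. From stage 9 to 10, 33 of the 91 rose again, but only 1 of the 27 highest at stage 3. Of the 30 with the reverse course 16 fell again. Whole siliques of stage 3 mixed into the stage 8 samples are argued against: over 54 probe sets high at stage 3 and low at seeds stages 7, 9 and 10, the excess at stage 8 had a median of 0.182% of the stage 3 signal and was under 1% for 43, while the 9 returning ones among them ranged from 1.19% to 14%. Seeds of stage 6 mixed in are argued against for 85 of the 91 probe sets, which lay above the stage 6 mean, 76 with all arrays apart. The selection for high values at stage 8 favours such a place too, so no share expected by chance is set beside these counts. The mixture is not argued against for the other 6, GILT among them (2310 ± 113 at stage 6, 1840 ± 130 at stage 8). A place above stage 7 was set by the selection and tests nothing. A part of a younger silique or younger seeds may be involved, or a response of the seeds at that harvest. No array here holds such material, so these stay open. A technical shift of the stage 8 arrays, which both steps share, stays open as well.

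Splitting the 6 arrays of a comparison in other ways gives 10 splits, too few for a share under 0.05. The real split was the 1 split with as many calls in each of the 9 comparisons. The real counts were 3614, 1972, 5735, 3200, 564, 594 and 3275, each with a highest other of 1, for siliques stage 5 against 3, seeds 6 against siliques 5, seeds 10 against 6, siliques 4 against 3 and 5 against 4, and seeds 7 against 6 and 8 against 7. For seeds 9 against 8 the real count was 623 and the highest other 13, and for seeds 10 against 9, 291 and 58. For the F test, 1 of 100 groupings, the real one, gave as many as 16103 probe sets, and the highest other gave 21. Random groupings mix the 8 groups and so widen the spread within a group, which made low counts likely beforehand. The result argues against a random arrangement of the arrays only. It decides nothing on technical differences between the groups.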

How the results depend on the processing

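The fits without the 6 arrays of high 25S signal and with the 25S signal as a covariate were chosen after the control probe sets were seen. Leaving out each array in turn kept every count within 1.5 times. Counts outside that range, of which the cause was not tested except where a changed threshold or offset makes it by construction, were these. For steps between consecutive stages higher and lower calls were counted together. Centring on the reference genes gave 4568 higher and 2173 lower for seeds stage 10 against 6. Taken by direction, this centring also moved seeds 8 against 7 from 1367 higher and 1908 lower to 3224 and 830. The lower calls of seeds 7 against 6 went from 182 to 296. Without an offset seeds 9 against 8 gave 1009 and 10 against 9 gave 614. With an offset 4 times larger, which shrinks low signals, seeds 6 against siliques 5 gave 422 higher and 778 lower, siliques 4 against 3 gave 2112 and 5 against 4 gave 312, and seeds 7 against 6, 8 against 7, 9 against 8 and 10 against 9 gave 332, 2039, 232 and 92. The overlap of the silique and seed calls in the same direction was then 374 and that of rises in siliques with falls in seeds 434, against 676 and 652. With no minimum fold siliques 5 against 3 gave 5002 higher and 5078 lower, seeds 6 against siliques 5 gave 4154 and 3540, seeds 10 against 6 gave 5942 and 6192, and the steps 3 to 4, 4 to 5, 6 to 7, 7 to 8, 8 to 9 and 9 to 10 gave 9374, 2946, 4151, 9839, 4754 and 3317, with overlaps of 3923 and 2082. Fry passed 29 list tests. Without the 6 arrays of high 25S signal seeds 10 against 9 gave 520, but stage 10 then has array B alone, other groups supply the spread, and nothing is read from it. With the title letters as a block every count stayed within 1.5 times, with 1936 higher and 2033 lower for siliques 5 against 3, 933 and 1316 for seeds 6 against siliques 5, 2357 and 3382 for seeds 10 against 6, and 15 lists. Letters D to F are linked to A to C only through array D of seeds stage 10. In this fit siliques 5 or 4 against 3 and seeds 6 against siliques 5 therefore rest on that 1 array. Their counts decide nothing on a batch tied to the letters. Deviations from the group means of arrays sharing a letter correlated across probe sets at -0.0538 to 0.102 over 45 pairs (median 0.0054), so the letters do not pair the arrays. Of 216 named gene results 158 kept direction and side of the threshold under all alternatives run on them, and of 33 list tests 16. Over all alternatives named genes gained a call 67 times, 44 of them with no minimum fold, and lost it 21 times, and lists gained it 21 times, 13 of them by fry, and lost it 16 times. Low signals limit what can be said, since the table has no detection calls and calls near the background follow the offset.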

Other observations

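All tests given here were chosen after the results were seen. Genes encoded in the organelles were counted without a test against other genes. Of 69 tested plastid genes 32 fell and none rose from siliques stage 3 to 5 (median -0.93), a fall that went along with lower pollen markers (median -2.45) and a lower actin 3'/5' ratio and was not separated from them. Of the same genes 10 rose and 1 fell from there to seeds stage 6 (median 0.56), and 5 rose and 6 fell from seeds stage 6 to 10, with a median of 0.14 that turned to -0.07 with quantile normalization. Of 13 mitochondrial genes 5 rose into seeds stage 6 (median 0.92) and 7 rose from stage 6 to 10 (median 1.09), none falling, and these medians stayed above 0 under all 3 scalings.

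Some gene families that had not been listed held more calls in 1 direction than other named genes, though of those given here only beta tubulin fell as a whole. Of 5 beta tubulin genes, for subunits of microtubules, all fell from seeds stage 6 to 10 (median -2.58, adjusted p = 0.0037), TUB6 at -2.84 and TUB7 at -2.58. From siliques stage 3 to 5, 6 of 10 RALF-like peptide genes fell (median -1.21, adjusted p = 0.0037), RALFL28 by 3.60 and RALFL26 by 3.47, while RALFL33 rose by 1.29. In the same comparison 8 of 18 trichome birefringence-like genes fell (median -0.79, adjusted p = 0.0037), TBL41 by 2.68, and TBL38 rose by 2.43. Of 11 glycosyl hydrolase 9 genes, which cut cellulose, 6 fell over the siliques (median -1.84, adjusted p = 0.0046) and 7 over the seeds (median -1.72, adjusted p = 0.01), GH9B8 by 4.52 over the seeds, and GH9C1 rose by 4.40 in the siliques. These falls over the siliques went along with those of the pollen markers (median -2.45) and with an actin 3'/5' ratio of 4.09 ± 0.288 (SD, n = 3) at stage 3 against 2.67 at stage 5, and were not separated from either. Of 33 UDP glycosyltransferase genes 12 rose from seeds stage 6 to 10 (median 0.45, adjusted p = 0.026), UGT72E1 by 5.68, and 9 fell, UGT73B1 by 3.21. The p-values are from Fisher's exact test of calls in the family against other named genes, adjusted over 72 tests of 8 families in each direction. The families were picked after the results were seen, and the adjustment does not cover families passed over. Members of a family are not independent either, so these p-values describe the families picked and do not establish an enrichment. The medians given here kept their sign under all 3 scalings.

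A hypothesis from the list figures is that late embryogenesis genes may rise later than storage and oil body genes. At seeds stage 6 the 8 storage and oil body genes stood at a mean of 88% of their log2 rise from siliques stage 3 to seeds stage 10, and the 14 late embryogenesis genes at 38.4% (exact permutation p = 9.1e-05, two-sided, 319770 assignments). The shares ran from 57% to 131%, the highest from OLEO3, which fell over the seed stages, and from 0.523% to 71.9%. The change of material from siliques to seeds lies inside this rise. Where the stage 3 signal was low, the share also depends on the offset. The medians were 87.5% and 43.4%, and since genes are not independent replicates the p describes these lists alone. The order was seen on these arrays before it was tested.

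A related hypothesis is that nuclear and plastid genes of the photosystems may part company over the seed stages. From seeds stage 6 to 10 the 6 tested nuclear genes had a median change of -3.67 and the 20 plastid genes a median of 0.09, a difference of 3.76 (exact permutation p = 0.00024, two-sided, 230230 assignments). No plastid gene lay below the highest nuclear gene, and the plastid median turned to -0.11 with quantile normalization. Plastid genes are transcribed in groups and many of their transcripts lack the poly(A) tail that labelling may favour, so they are neither independent nor measured quite like nuclear ones.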
